A study of Mus musculus with 6 samples.

How the data were processed

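Gene expression was measured in whole liver of wild-type male C57Bl/6 mice with the Affymetrix Mouse Genome 430A 2.0 array, a 1-colour array hybridised with biotin-labelled RNA. Mice had received vehicle, purified FGF15 or recombinant FGF19 through the jugular vein, and livers were taken after 6 h without food and frozen in liquid nitrogen. There were 6 arrays, 2 per group, and each array was placed in its group by its title. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical. The dose of either protein and the composition of the vehicle are not given in the sources used here.

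The values analysed were the deposited signal intensities, 1 per probe set and array, on a linear scale. Per the values themselves, the authors had scaled each deposited array to a mean signal intensity, after trimming 2% at each end, of about 200 (199.98 on every array). The software that summarised probes into probe sets, its version and any detection call are not given in the sources used here. No further scaling was applied. Signals were converted to log2(signal + 32), and fold changes are on that scale, so they understate the change of genes with low signals. The array held 22690 probe sets, of which 64 were controls. The platform annotation paired 20380 probe sets with 1 gene symbol and 691 with several, and 1555 besides the controls were listed with none. Of the probe sets with 1 gene, 20351 were named through their Entrez identifier and 29 kept the platform symbol. Probe sets with several genes or none were given no gene name. They were tested only at the level of probe sets. The 12393 genes with a probe set of their own were each represented by the probe set of highest mean over all 6 arrays. Genes under the 25th percentile of mean log2 value over all probe sets, a mean signal of about 14.0, were left out. This removed 2708 genes and left 9685.

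Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), in a single model of all 6 arrays with group as its only term. The groups share an estimate of the spread, with 3 residual and 6.83 prior degrees of freedom. The 4 contrasts were FGF15 minus vehicle, FGF19 minus vehicle, FGF19 minus FGF15, and the mean of both FGFs minus vehicle. Tests were two-sided with Benjamini-Hochberg adjustment over the genes of a contrast, and a gene is said to rise, fall or change at an adjusted p under 0.05. Every adjusted p given for a gene is from this limma fit, and errors of fold changes are limma's standard errors with n = 2 arrays per group. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.13. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

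There were 25 lists of pathway genes and 10 lists of markers of cell types or tissues that whole liver can hold. They had 707 entries, of which 586 passed the filter and 83 had no probe set paired with that gene alone. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of each family (pathways or markers) in a contrast. Camera asks whether a list moved relative to all other genes. It was repeated with a correlation estimated from the data, and fry was run beside it. The estimate lay under the preset value for some lists and over it for others. A call lost with the estimate is therefore not always lost to a higher correlation, and what else ended such calls was not tested. Calls of single members were also counted with the adjustment taken over the list alone. Some genes stand in more than 1 list. The genes named were the 10 that rose and the 10 that fell most with each FGF against vehicle, the 5 each way for the other 2 contrasts, up to 4 members of each list with the smallest p against vehicle, and 19 measured genes fixed by name. To be taken by size, a gene had to pass the test and have all arrays of its groups apart. Together these were 206 genes. Asns, Fkbp5 and 4 list members that moved against their lists (Acox2, Angptl4, Thrsp and Klf15) were named after their values were seen. Probe sets ending in _s_at or _x_at can hybridise with related transcripts and are named with that limit.

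The groups, contrasts, lists, rule for named genes and all alternatives except cyclic loess normalization were fixed before the data were examined. The alternatives were a smaller and a larger pseudocount, quantile normalization, centring of each array on its median, no filter or a stricter one on low signals, the mean of all probe sets of a gene, all probe sets, other variance priors, only the arrays compared, the replicate number as a block, array weights, a threshold of 0.10 and each array left out in turn. A value given without either array of a group holds whichever one of them is left out. Cyclic loess was added after seeing the data. The steps were tested on simulated data made from the real means with 200 changed genes. These were drawn from tested genes above the 25th percentile of mean log2 value, and the noise of each gene was drawn independently. In the FGF15 contrast, 68.7% of genes changed 1.5-fold were recovered, 98.5% of those changed 2-fold and 100.0% of those changed 4-fold, with 11 false calls among 9685 genes. In the FGF19 contrast the shares were 80.6%, 100.0% and 100.0%, with 15 false calls. In the simulated FGF15 contrast, 1 of 25 lists was called, the list that had been shifted. With independent noise this does not show how many false list calls correlated genes would give.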

Results

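Whole-liver RNA from wild-type male mice was profiled 6 h after an injection of vehicle, FGF15 or FGF19 into the jugular vein, with 2 arrays per group and 6 in all. FGF15 and its human orthologue FGF19 are hormones of the ileum, released when bile acids are taken up after a meal. In liver they act through the receptor FGFR4 and its co-receptor β-Klotho. The comparisons ask which liver transcripts differ from vehicle with each hormone and whether the responses to the hormones differ.

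The median signal was 61.4 and 59.4 on the vehicle arrays, 55.2 and 51.3 on the FGF15 arrays and 50.8 and 52.2 on the FGF19 arrays, after scaling to one trimmed mean. Between 36.4% and 41.5% of the probe sets of an array lay under a signal of 32. Across genes, which are not independent replicates, log2 values of the arrays of a group correlated at r = 0.989 for vehicle, 0.989 for FGF15 and 0.992 for FGF19, and arrays of different groups at 0.975 to 0.986. The median SD between the arrays of a group was 0.08 for vehicle, 0.09 for FGF15 and 0.09 for FGF19 on the log2 scale. FGF19 replicate 1 stood apart in the control probe sets. Its 18S rRNA control read 32.3 against 4.25 to 5.82 on the other arrays, and its 3' to 5' ratio, which rises as RNA degrades, was 1.63 for β-actin against 1.30 to 1.39, and 3.38 for pyruvate carboxylase against 2.27 to 2.73. Its spiked-in controls had a geometric mean of 688 against 796 to 957.

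FGF15 was set against vehicle first. Cyp7a1 (probe set 1438743_at), the rate-limiting enzyme of bile acid synthesis, had a mean signal of 2625 ± 74.4 with vehicle and 90.5 ± 1.53 with FGF15 (SD, n = 2), 21.7-fold lower. Moxd1 (1422643_at), which encodes a monooxygenase-like protein, fell from 1633 ± 73.1 to 5.78 ± 6.23 and Tff3, a secreted trefoil peptide, from 459.9 ± 14.6 to 16.6 ± 15.8. The gluconeogenic genes G6pc and Ppargc1a fell 2.49-fold and 3.74-fold, while Nr0b2, which encodes the repressor SHP, doubled (2.03-fold) and Rgs16, a regulator of G protein signalling, rose 5.19-fold. Other probe sets gave smaller changes, at log2 values of -1.11 to -1.33 for Ppargc1a and 1.78 and 1.51 for Rgs16. Most changed genes of fatty acid oxidation and of the endoplasmic reticulum stress response rose, and markers of Kupffer cells, the macrophages of the liver, fell as a group. The first 2 lists were called at a preset correlation, but each had an adjusted p = 0.0684 with an estimated correlation, against adjusted p = 0.0302 for the Kupffer cell markers. The markers were adjusted over 7 lists and the pathways over 25, so these values cannot be compared directly. For the first 2 lists the estimates (-0.0304 and -0.0309) lay under the preset value, so a higher correlation does not explain these lost calls.

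The log2 change with FGF15 was -4.44 ± 0.09 for Cyp7a1 (SE, adjusted p = 3.2e-09), -5.47 ± 0.15 for Moxd1 (adjusted p = 3.8e-08) and -3.38 ± 0.19 for Tff3 (adjusted p = 4.7e-06). The mean signal of Moxd1 with FGF15 lay under the level of the filter on low signals and that of Tff3 close to it, so these changes are set by the offset of 32 and understate the fall. Among the other genes that fell most, Dmbt1, a mucosal scavenger protein, changed by -2.05 ± 0.15, the acute phase genes Saa3 and Orm2 by -1.90 ± 0.08 and -1.70 ± 0.06, Ddc (aromatic amino acid decarboxylase) by -1.89 ± 0.11, the organic anion transporter gene Slc22a7 by -1.57 ± 0.08, and Fabp5 by -1.57. The genes that rose most included Rgs16 (2.38 ± 0.11), Acot3 (2.22 ± 0.16), an acyl-CoA thioesterase whose probe set (1422925_s_at) can also bind related transcripts, Cyp26a1, which degrades retinoic acid (2.18 ± 0.11), Cyp4a14, a fatty acid hydroxylase (1.97 ± 0.06), and Cyp2b9 (1.72 ± 0.14). For Egr1, an immediate early transcription factor, the mean signal was 96.7 ± 16.4 with vehicle and 318.4 ± 4.25 with FGF15, 2.73-fold higher (adjusted p = 7.4e-06), and Dusp6, a phosphatase induced by ERK signalling, rose 2.22-fold. In all of these genes both FGF15 arrays lay on the same side of both vehicle arrays. This was a condition for genes taken by size and held for every gene called with FGF15, so it adds no support.

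**Figure D1:**
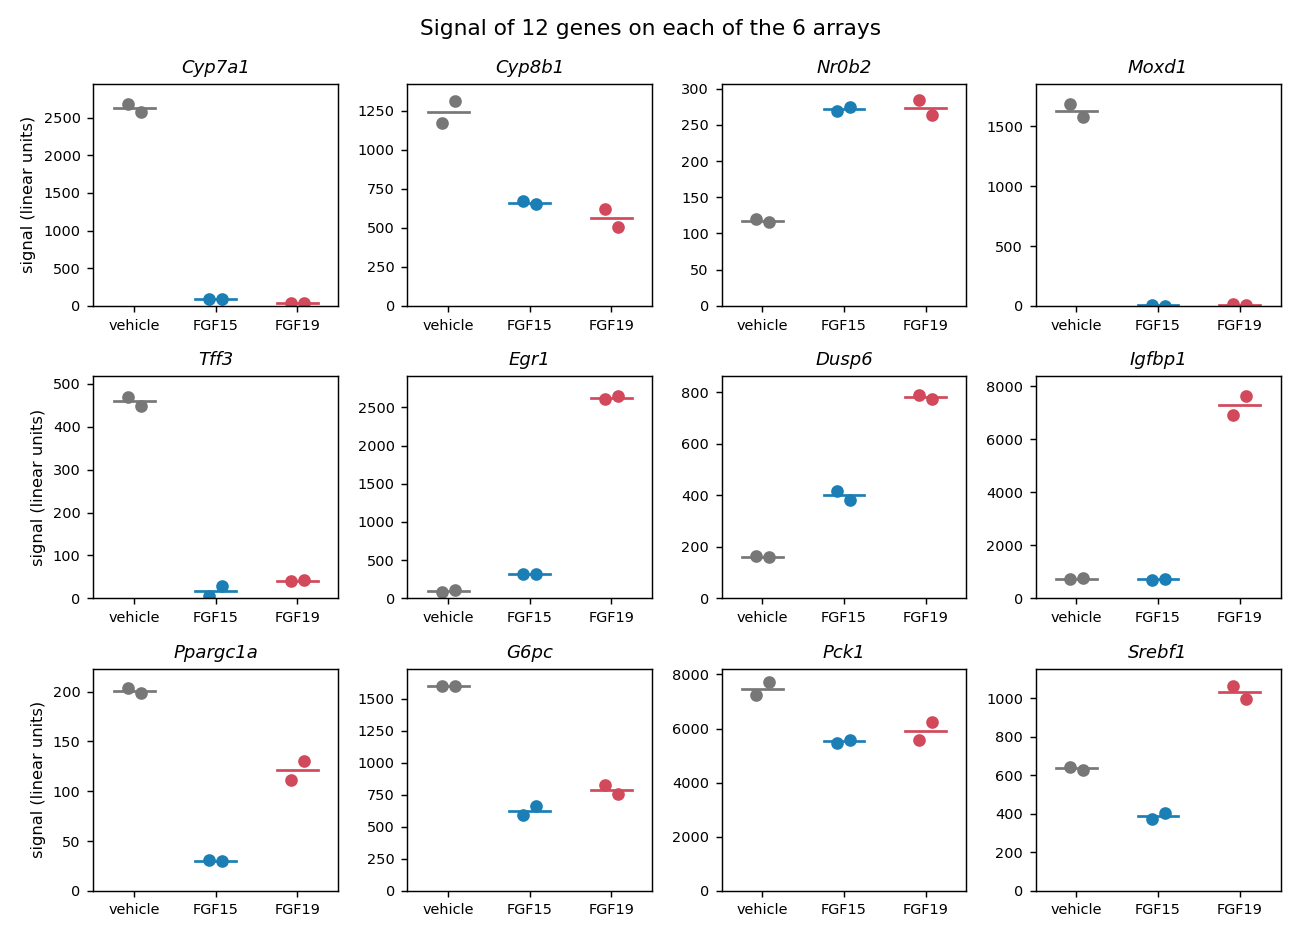
Signal (linear scale, arbitrary units) of 12 genes on each array, by group; points are arrays and lines are group means (n = 2). Cyp7a1 lies at 2625 with vehicle, 90.5 with FGF15 and 35.2 with FGF19, and Igfbp1 at 746.5, 725.6 and 7278.

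Of 16 measured genes of bile acid synthesis, 5 fell and 1 rose with FGF15, and 5 fell and 2 rose when adjusted over the list alone. The list was called lower (camera adjusted p = 0.00722, and adjusted p = 0.191 with an estimated correlation), although its median of -0.11 turned to 0.01 when arrays were centred on their medians. Besides Cyp7a1, Cyp8b1, which sets the share of cholic acid, fell 1.84-fold (log2 change -0.88 ± 0.10, adjusted p = 0.00029), Cyp7b1, of the alternative pathway, 2.23-fold (adjusted p = 4.1e-06) and Cyp2c70, which makes muricholic acids, 1.43-fold (adjusted p = 0.00069). The riser was Acox2, of side chain oxidation (0.31 ± 0.08, adjusted p = 0.041), named after its values were seen. Among 14 receptors and regulators of bile acid and FGF signalling, 1 rose and 3 fell, 1 and 4 when adjusted over the list alone (camera adjusted p = 0.531). The number that fell was 1 with centring on medians or without vehicle replicate 2, and 0 without vehicle replicate 1 or FGF15 replicate 1. The riser was Nr0b2 (1.02 ± 0.09, adjusted p = 7.4e-05). Klb, which encodes β-Klotho, fell by 0.41 ± 0.11 (adjusted p = 0.041). That call ended without vehicle replicate 1 (adjusted p = 0.123), vehicle replicate 2 (0.177), FGF15 replicate 1 (0.0790) or FGF15 replicate 2 (0.157), and with centring on medians (0.131). The change of Fgfr4 was -0.27 ± 0.12 (adjusted p = 0.2).

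Of 27 genes of fatty acid oxidation and ketogenesis, 15 rose and 1 fell with FGF15, 17 and 1 when adjusted over the list alone (camera adjusted p = 3.61e-14, and adjusted p = 0.0684 with an estimated correlation). Cyp4a14 rose 3.92-fold, Vnn1 3.29-fold, the fatty acid transporter Cd36 2.52-fold and the lipid droplet gene Plin2 1.95-fold. Cpt1a, the carnitine palmitoyltransferase of mitochondrial entry, and Pdk4 did not pass (0.07 ± 0.07 and 0.01 ± 0.15), and Angptl4, named after its values were seen, fell by 0.37 ± 0.10, a call that ended without any one vehicle or FGF15 array. Of 24 genes of endoplasmic reticulum stress and ATF4, 10 rose and 1 fell, 15 and 1 when adjusted over the list alone (camera adjusted p = 9.55e-10, and adjusted p = 0.0684 with an estimated correlation). The chaperone genes Creld2, Sdf2l1, Dnajb9 and the ER-associated degradation gene Herpud1 rose 3.21-fold, 2.84-fold, 2.62-fold and 2.20-fold. With centring on medians 16 of them rose. The member that fell was Asns, asparagine synthetase, an ATF4 target named after its values were seen (-1.52 ± 0.11, adjusted p = 2.1e-05).

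Of 19 lipogenic genes, 8 rose and 2 fell with FGF15, the same numbers as when adjusted over the list alone (camera adjusted p = 4.97e-05, and adjusted p = 0.191 with an estimated correlation). Me1 rose 1.96-fold, Elovl6 1.88-fold, Acly 1.55-fold and Elovl5 1.47-fold. Srebf1, the transcription factor of the pathway, fell 1.59-fold (-0.67 ± 0.07, adjusted p = 0.00026), as did Thrsp, named after its values were seen (-0.39 ± 0.08, adjusted p = 0.0096). Fasn, fatty acid synthase, rose by 0.33 ± 0.07 (adjusted p = 0.012), a call that ended without vehicle replicate 1 (0.128), vehicle replicate 2 (0.0523) or FGF15 replicate 2 (0.0914), and Scd1 did not pass (-0.05 ± 0.12, adjusted p = 0.82).

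Of 18 genes responsive to fasting and cAMP, 8 fell and 1 rose with FGF15, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.000228, and adjusted p = 0.174 with an estimated correlation). The coactivator gene Ppargc1a had a mean signal of 201.0 ± 3.81 with vehicle and 30.3 ± 0.908 with FGF15 (adjusted p = 8.2e-06), Lpin1 fell 2.26-fold, and Crem was the riser (0.39 ± 0.08, adjusted p = 0.013, but 0.104 without vehicle replicate 1 and 0.0608 without FGF15 replicate 2, and 0.09 on the log2 scale on another probe set). With centring on medians, or without either vehicle array, 5 of the list fell. G6pc, the glucose-6-phosphatase of glucose release, fell from 1603 ± 1.46 to 626.0 ± 49.6 (adjusted p = 4.8e-06). Pck1, of the first committed step, fell 1.35-fold (adjusted p = 0.0049, 0.0717 without vehicle replicate 2), and Fbp1 did not pass (0.01, 95% interval -0.18 to 0.19). Of 14 gluconeogenic genes, 6 fell and 2 rose, the same numbers as when adjusted over the list alone (camera adjusted p = 0.069), and their median of -0.07 turned to 0.04 with centring on medians. At most 1 of them rose without any one vehicle or FGF15 array. Of 18 glucocorticoid-responsive genes, 8 fell and 1 rose, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.000585, and adjusted p = 0.191 with an estimated correlation). The number that fell was 4 with centring on medians, 2 without vehicle replicate 1, 3 without vehicle replicate 2 or FGF15 replicate 1 and 5 without FGF15 replicate 2. The fallers included Cdkn1a, which encodes a cell cycle inhibitor (2.13-fold), and the riser was Slc16a1 (0.27 ± 0.07, adjusted p = 0.037). That rise ended without vehicle replicate 1 (0.263), vehicle replicate 2 (0.0554), FGF15 replicate 1 (0.121) or FGF15 replicate 2 (0.114).

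Of 21 cell cycle genes, 7 fell and 0 rose with FGF15, 10 and 0 when adjusted over the list alone (camera adjusted p = 0.00229, and adjusted p = 0.191 with an estimated correlation). Ccnd1, cyclin D1, fell 1.77-fold. Mcm2, of the replicative helicase, and Rrm2, of deoxynucleotide synthesis, fell 1.98-fold and 1.62-fold on probe sets that can bind related transcripts (_s_at and _x_at; other probe sets of Rrm2 gave -0.14 and -0.53), and the inhibitor Cdkn1a fell as well. The cell cycle call ended with the stricter filter on low signals (0.0683), which gave 8 called pathway lists with FGF15 against 12 in the main fit. Of 25 inflammatory and interferon genes, 5 fell and 1 rose, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00905, and adjusted p = 0.255 with an estimated correlation), with Irf7 1.82-fold, Vcam1 1.63-fold and Psmb8 1.62-fold lower and Cxcl1 as the riser (0.23 ± 0.06, adjusted p = 0.044). Without either vehicle array 3 fell. The rise of Cxcl1 ended without vehicle replicate 1 (0.155), vehicle replicate 2 (0.25), FGF15 replicate 1 (0.0977) or FGF15 replicate 2 (0.22). Of 21 genes of xenobiotic and heme metabolism, 5 rose and 3 fell, 7 and 4 when adjusted over the list alone (camera adjusted p = 0.0249, and adjusted p = 0.191 with an estimated correlation), with Cyp2b9 3.30-fold and Gsta2 2.87-fold higher and Alas1, of heme synthesis, 1.44-fold lower. Cyp2b10 rose 2.49-fold on an _s_at probe set. The xenobiotic list lost its call with the stricter filter (0.0683) and with cyclic loess (0.066), which gave 10 called pathway lists in all. In that list 1 fell without either vehicle array or with centring on medians, and 5 fell without either FGF19 array. Of 19 genes of the growth hormone and IGF axis, 4 fell and 0 rose, 6 and 0 when adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.191 with an estimated correlation). That call ended without vehicle replicate 2 (0.129) or FGF15 replicate 1 (0.132). The number that fell was 2 with centring on medians or without either FGF15 array, 0 without vehicle replicate 1, 1 without vehicle replicate 2 and 7 without either FGF19 array. Lists also called higher were heat shock proteins, with 5 of 18 up and 2 down (6 and 2 when adjusted over the list alone), at camera adjusted p = 0.0251 and adjusted p = 0.44 with an estimated correlation, and oxidative phosphorylation and TCA cycle, with 2 of 32 up and 1 down (1 and 1, and 7 up with centring on medians, 4 without either FGF19 array and 0 or 1 without any one vehicle or FGF15 array), at 0.0146 and adjusted p = 0.255 with an estimated correlation. Both calls ended without vehicle replicate 1 (0.0890 and 0.126), without FGF15 replicate 2 (0.139 and 0.0802) and with quantile normalization (0.12 and 0.123).

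The other lists were not called with FGF15. Of 30 acute phase genes, 3 rose and 8 fell, 5 and 10 when adjusted over the list alone (camera adjusted p = 0.27), but 6 rose and 5 fell with centring on medians. The numbers were 2 and 4 without vehicle replicate 1, 3 and 5 without vehicle replicate 2, and 5 and 14 without either FGF19 array, which enter this comparison through the shared spread alone. Steap4 rose 2.01-fold against the falls of Saa3 and Orm2. Of 22 immediate early genes, 1 rose, Egr1, and 2 fell, the same numbers as when adjusted over the list alone (0.828), and Fos did not pass (0.00 ± 0.15). Of 13 targets of ERK and FGF signalling, 2 rose and 1 fell, 3 and 1 when adjusted over the list alone (0.352). Of 13 transporters of bile acids and sterols, 1 rose, Abcc3 (1.73-fold), and 3 fell, 2 and 3 when adjusted over the list alone (0.52), with Slco1a4 1.64-fold lower. Of 19 genes of cholesterol synthesis, 0 rose and 4 fell, the same when adjusted over the list alone (0.294), with a median that turned from -0.09 to 0.03 with centring on medians. Rises and falls were 3 and 1 of 15 in glycogen metabolism (3 and 1 when adjusted over the list alone, 0.352), 1 and 1 of 28 in ribosome biogenesis (1 and 1, 0.352), 1 and 1 of 19 in translation (1 and 1, 0.828), 1 and 3 of 17 in the circadian clock (1 and 4, 0.713), 3 and 3 of 24 in amino acid catabolism (5 and 4, 0.884) and 3 and 2 of 15 among NRF2 targets (3 and 4, 0.963), where Srxn1 fell 2.85-fold on an _s_at probe set and Hmox1 2.13-fold. Gys2, liver glycogen synthase, rose by 0.44 ± 0.08 (adjusted p = 0.0077, but 0.0605 without vehicle replicate 1 and 0.0561 without vehicle replicate 2). Medians, means and test directions differed in sign for translation, ERK targets, glycogen metabolism and NRF2 targets. Over the fits that left out 1 array, 0 to 4 genes of cholesterol synthesis fell, 0 to 3 of glycogen metabolism and 0 to 5 of amino acid catabolism rose and 0 to 2 immediate early genes fell, lowest without a vehicle array. With centring on medians 4 ERK targets and 5 genes of amino acid catabolism rose.

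**Figure D2:**
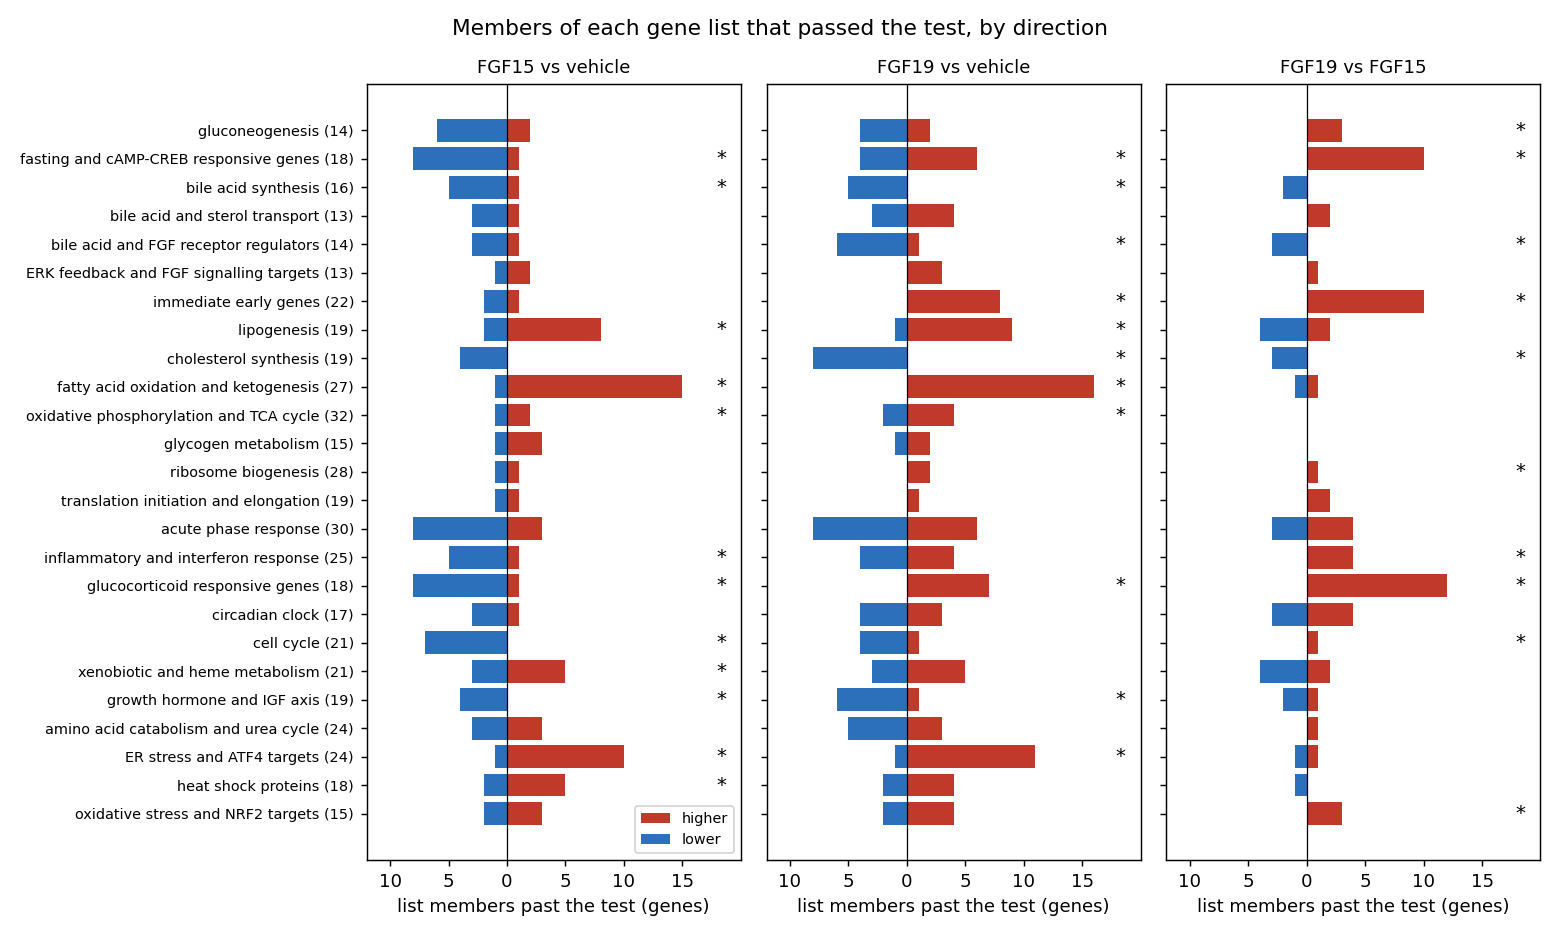
Members of each gene list that rose (bars to the right) or fell (bars to the left) in 3 comparisons, as numbers of genes, with the number measured in brackets and a star where camera gave an adjusted p under 0.05 (2 arrays per group). With FGF15, 15 of 27 genes of fatty acid oxidation rose, and 12 of 18 glucocorticoid-responsive genes were higher with FGF19 than with FGF15.

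Markers of Kupffer cells and macrophages fell with FGF15 beside the inflammatory genes. Of 12 measured, 11 fell and 0 rose, 12 and 0 when adjusted over the list alone, with a median log2 change of -0.72 (camera adjusted p = 7.2e-13, and adjusted p = 0.0302 with an estimated correlation). Mpeg1 fell 2.31-fold, Vsig4 1.82-fold, Clec4f 1.72-fold and C1qc 1.67-fold. Of 5 neutrophil markers, 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.0225, and adjusted p = 0.224 with an estimated correlation), with S100a9 1.76-fold lower. Marker lists of other cell types were not called. Of 13 endothelial markers 1 fell (0.337), with a median of -0.05 that turned to 0.07 with centring on medians. Of 12 stellate cell and fibroblast markers 4 fell, or 5 with 1 up when adjusted over the list alone (0.0534), among them the collagen gene Col3a1 (2.03-fold), and 2 fell without either vehicle array. Falls numbered 2 of 13 for lymphocytes (0.103) and 1 of 7 for cholangiocytes (0.337), and 1 of 12 hepatocyte markers rose and 1 fell (0.337), or 1 and 5 without either FGF19 array. Lists with fewer than 5 measured members were not tested. Of these, 0 of 4 erythroid and 0 of 4 pancreatic markers changed and 1 of 3 adipose markers fell.

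In all, 1218 of 9685 genes changed with FGF15, 572 up and 646 down, of which 37 rose and 54 fell more than 2-fold, and 12 of 25 pathway lists were called, 6 in each direction, and 0 with an estimated correlation. At an unadjusted p under 0.05 there were 2529 genes. Both FGF15 arrays lay on one side of both vehicle arrays in 5324 genes (55.0%, where chance gives 33.3%), including all 1218. The split depends on scaling, since centring arrays on their medians moved the median change of all genes from -0.05 to 0.07 and gave 1007 up and 356 down. Some genes named with FGF15 differed in size on another probe set, with log2 changes of 1.65 against 0.97 for Me1, -1.22 against -0.53 for Alas1, 0.73 against 1.33 for Cd36 and, on dim probe sets, -0.17 against -1.51 for Srxn1 and -0.24 against -1.02 for Col3a1. A further probe set of Cd36, brighter than the one at 0.73, read 1.19. Without vehicle replicate 1 the number of changed genes was 538, without vehicle replicate 2 it was 606 and without FGF15 replicate 2 it was 722.

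With FGF19, Cyp7a1 reached a mean signal of 35.2 ± 4.33 (SD, n = 2) against 2625 ± 74.4 with vehicle, 39.6-fold lower on the log2(signal + 32) scale. Moxd1 (10.2 ± 5.82, under the level of the filter on low signals) and Tff3 (41.3 ± 2.5) again had low signals. The largest rises were those of Egr1, from 96.7 ± 16.4 to 2625 ± 24.9, and of Igfbp1, which encodes an IGF binding protein secreted by liver, from 746.5 ± 9.06 to 7278 ± 499. At the preset correlation the lists of immediate early and glucocorticoid-responsive genes, fatty acid oxidation, ER stress and lipogenesis were called higher with FGF19 and cholesterol synthesis lower. None of these held with an estimated correlation and adjustment over 25 lists (adjusted p = 0.0762, 0.157, 0.0608, 0.0608, 0.193 and 0.216, in that order). The fall of the Kupffer cell markers held (adjusted p = 0.0435), but with adjustment over 7 lists, so these values cannot be compared directly. The estimates were -0.021, 0.0251, -0.0304, -0.0309, 0.0749 and 0.0496, in the same order. Those of immediate early genes, fatty acid oxidation and ER stress lay under the preset value. A higher correlation therefore does not explain why these lists lost their calls, and the cause was not tested.

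The log2 change with FGF19 was 4.37 ± 0.09 for Egr1 (SE, adjusted p = 2.3e-09), 3.23 ± 0.07 for Igfbp1 (adjusted p = 2.3e-09), -5.31 ± 0.09 for Cyp7a1 (adjusted p = 5.5e-10), -5.31 ± 0.15 for Moxd1 (adjusted p = 2.6e-08) and -2.75 ± 0.19 for Tff3 (adjusted p = 1.5e-05), those of Moxd1 being set by the offset of 32. Rgs16 (2.19 ± 0.11), Dusp6 (2.07 ± 0.08), Btg2 (1.98 ± 0.08), Cyp4a14 (1.92 ± 0.06), Gsta2 (1.84 ± 0.07) and Tiparp (1.84 ± 0.09) rose as well, as did Pltp, phospholipid transfer protein, whose probe set (1456424_s_at) can bind related transcripts (1.71 ± 0.07, and 0.595 on another probe set). Slc22a7 (-2.04 ± 0.08), Orm2 (-1.99 ± 0.06), the 3-beta-hydroxysteroid dehydrogenase gene Hsd3b5 (-1.86) and Usp2 (-1.64) were among the genes that fell most. Others were Erdr1, on an _x_at probe set (-1.68 ± 0.07), and Dbp, a clock-controlled transcription factor, on an _s_at probe set (-1.54 ± 0.08). In each, both FGF19 arrays lay on the same side of both vehicle arrays, again a condition for genes taken by size and true of every gene called with FGF19.

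Of 22 immediate early genes, 8 rose and 0 fell with FGF19, 9 and 0 when adjusted over the list alone (camera adjusted p = 3.58e-07, and adjusted p = 0.0762 with an estimated correlation). Without FGF19 replicate 1, the array that stood apart in its control probe sets, 7 rose. Ier2 rose 3.04-fold, Fos 2.26-fold (1.17 ± 0.15, adjusted p = 0.00059) and Zfp36, which encodes an mRNA decay factor, 1.74-fold. Of 18 glucocorticoid-responsive genes, 7 rose and 0 fell, 7 and 1 when adjusted over the list alone (camera adjusted p = 2.1e-05, and adjusted p = 0.157 with an estimated correlation), and again 7 rose without FGF19 replicate 1. They included Igfbp1, the kinase gene Sgk1 (1.82-fold) and Cdkn1a (1.76-fold, but 0.18 on the log2 scale on its other probe set), while Fkbp5, a direct glucocorticoid receptor target named after its values were seen, did not pass (-0.06 ± 0.07, adjusted p = 0.61). Of 18 fasting and cAMP genes, 6 rose and 4 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.0429, and adjusted p = 0.216 with an estimated correlation). The call ended without FGF19 replicate 2 (0.201), with centring on medians (0.0643) and with the stricter filter on low signals (0.147). The number that fell was 1 without either vehicle array and 2 without FGF19 replicate 1 or with centring on medians. Igfbp1 and Id1 (2.62-fold) rose, and Ppargc1a, Pck1, G6pc and Klf15, the last named after its values were seen, fell.

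G6pc fell from 1603 ± 1.46 to 790.2 ± 52 with FGF19, 1.99-fold (adjusted p = 2.5e-05). Ppargc1a fell 1.53-fold (adjusted p = 0.0086), a call that ended without vehicle replicate 1 (0.0679), vehicle replicate 2 (0.0528) or FGF19 replicate 1 (0.0790). Pck1 fell 1.26-fold (adjusted p = 0.016), which ended without vehicle replicate 1 (0.0778) or vehicle replicate 2 (0.144) and with centring on medians (0.19). Fbp1 did not pass (-0.14, 95% interval -0.32 to 0.05), but passed without FGF19 replicate 2 (-0.25, adjusted p = 0.0186). Of 14 gluconeogenic genes, 4 fell and 2 rose, the same numbers as when adjusted over the list alone (camera adjusted p = 0.485), and their median turned from -0.12 to 0.02 with centring on medians, when 2 fell and 4 rose. Without FGF19 replicate 1, 2 fell and the median was -0.06, and without either vehicle array 1 fell.

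Of 16 genes of bile acid synthesis, 5 fell and 0 rose with FGF19, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00257, and adjusted p = 0.193 with an estimated correlation), and 8 fell without FGF19 replicate 2. Cyp8b1 had a mean signal of 1244 ± 103 with vehicle and 562.3 ± 79.4 with FGF19, 2.15-fold lower (adjusted p = 5.5e-05), Cyp7b1 fell 2.31-fold (adjusted p = 2.1e-06) and Cyp2c70 1.82-fold (adjusted p = 2.1e-05). Of 14 regulators and receptors, 6 fell and 1 rose, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.216 with an estimated correlation). The number that fell was 3 with centring on medians, 2 without vehicle replicate 1 or FGF19 replicate 2 and 1 without vehicle replicate 2. Nr0b2 was the riser (1.03 ± 0.09, adjusted p = 5.8e-05), and Nr1h4, which encodes the bile acid receptor FXR, fell 1.82-fold (adjusted p = 6.2e-05). Fgfr4 fell by 0.45 ± 0.12 (adjusted p = 0.039) and Klb by 0.45 ± 0.11 (adjusted p = 0.028). Without vehicle replicate 1, vehicle replicate 2 or FGF19 replicate 2 the call of Klb ended (0.0949, 0.13 and 0.168), as it did with centring on medians (0.115), and that of Fgfr4 ended without vehicle replicate 1 (0.198), vehicle replicate 2 (0.0885), FGF19 replicate 1 (0.0701) or FGF19 replicate 2 (0.2) and with centring (0.132). Of 19 genes of cholesterol synthesis, 8 fell and 0 rose, the same as when adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.216 with an estimated correlation), and 3 fell with centring on medians, 4 without either vehicle array and 5 without FGF19 replicate 1. Sqle fell 1.85-fold, Dhcr7 1.42-fold and Hmgcs1 1.59-fold, the last on an _x_at probe set.

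Of 27 genes of fatty acid oxidation, 16 rose and 0 fell with FGF19, 17 and 0 when adjusted over the list alone (camera adjusted p = 4.43e-12, and adjusted p = 0.0608 with an estimated correlation), and 9 rose without vehicle replicate 1. Cyp4a14 rose 3.79-fold, Cd36 2.52-fold, Vnn1 2.47-fold and Plin2 2.19-fold. Pdk4 rose by 0.63 ± 0.15 (adjusted p = 0.024), which ended without vehicle replicate 1 (0.151), FGF19 replicate 1 (0.16) or FGF19 replicate 2 (0.0589), and Cpt1a did not pass (-0.06 ± 0.07). Of 24 genes of ER stress and ATF4, 11 rose and 1 fell, 13 and 1 when adjusted over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.0608 with an estimated correlation), with Creld2 3.07-fold, Sdf2l1 2.40-fold and Herpud1 2.20-fold higher. Asns was the member that fell (-0.49, adjusted p = 0.017), a call that ended without vehicle replicate 1 (0.124), vehicle replicate 2 (0.0615), FGF19 replicate 1 (0.0790) or FGF19 replicate 2 (0.0942) and with centring on medians (0.0701). Of 19 lipogenic genes, 9 rose and 1 fell, 11 and 1 when adjusted over the list alone (camera adjusted p = 9.5e-06, and adjusted p = 0.193 with an estimated correlation), and 5 rose without vehicle replicate 1 and 4 without vehicle replicate 2. Fasn rose 1.80-fold (adjusted p = 3.8e-05), Me1 2.13-fold and Srebf1 1.59-fold (0.67 ± 0.07, adjusted p = 0.00024), while Thrsp fell by 0.29 ± 0.08 (adjusted p = 0.034). Scd1 did not pass (-0.19 ± 0.12), but passed without FGF19 replicate 2 (-0.39, adjusted p = 0.00378). Gys2 rose 1.47-fold (adjusted p = 0.002).

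Of 19 genes of the growth hormone and IGF axis, 6 fell and 1 rose with FGF19, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.216 with an estimated correlation). The call ended without vehicle replicate 2 (0.165), and 2 fell and 1 rose with centring on medians or without either vehicle array. Socs2 and Igfals fell 2.20-fold and 1.84-fold, and the riser was Igfbp1. Oxidative phosphorylation and TCA cycle, with 4 of 32 up and 2 down (6 and 2 when adjusted over the list alone, and 11 up with centring on medians, 0 without either vehicle array, 2 without FGF19 replicate 1 and 1 without FGF19 replicate 2), was called higher at 0.0429, and adjusted p = 0.288 with an estimated correlation. It lost the call without vehicle replicate 1 (0.227) or FGF19 replicate 2 (0.134) and with quantile normalization (0.372). The remaining lists were not called. Rises and falls were 5 and 3 of 21 in xenobiotic and heme metabolism (7 and 6 when adjusted over the list alone, camera adjusted p = 0.0517), 6 and 8 of 30 acute phase genes (7 and 13, 0.351), 4 and 4 of 25 inflammatory genes (4 and 8, 0.7), 3 and 4 of 17 circadian genes (3 and 7, 0.572), 1 and 4 of 21 cell cycle genes (1 and 5, 0.284), 4 and 3 of 13 transporters (4 and 4, 0.572), and 3 and 0 of 13 ERK targets (3 and 1, 0.17). They were 2 and 1 of 15 in glycogen metabolism (3 and 1, 0.284), 2 and 0 of 28 in ribosome biogenesis (2 and 0, 0.246), 1 and 0 of 19 in translation (1 and 0, 0.186), 3 and 5 of 24 in amino acid catabolism (3 and 5, 0.942), 4 and 2 of 18 heat shock proteins (4 and 4, 0.351) and 4 and 2 of 15 NRF2 targets (6 and 4, 0.134). With centring on medians the balance turned to more rises than falls among acute phase genes (9 and 4), amino acid catabolism (6 and 0), circadian genes (3 and 2) and inflammatory genes (6 and 3), and 6 genes of glycogen metabolism, 5 of translation and 7 NRF2 targets rose. Without FGF19 replicate 1 the numbers were 3 and 3 in xenobiotic metabolism, 1 and 3 of inflammatory genes, 1 and 1 of cell cycle genes, 2 and 3 of transporters, 1 and 0 of ERK targets, 1 and 2 in amino acid catabolism, 2 and 2 of heat shock proteins and 2 and 2 of NRF2 targets. Without FGF19 replicate 2, 16 acute phase genes, 8 of amino acid catabolism, 6 of xenobiotic metabolism and 1 of the cell cycle fell. Without either vehicle array, 4 acute phase genes, 2 circadian genes, 1 transporter and 1 gene of amino acid catabolism fell. Among these lists, Irf7 fell 1.67-fold, Vcam1 1.51-fold (-0.13 and -0.70 on the log2 scale on other probe sets) and Rora rose 2.34-fold, and the riser of the cell cycle list was the inhibitor Cdkn1a, where 2 rose and 2 fell with centring on medians. Median and test direction differed in sign for the transporters.

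Kupffer cell and macrophage markers were lower with FGF19 too. Of 12, 10 fell and 0 rose, the same as when adjusted over the list alone, with a median of -0.76 (camera adjusted p = 3.95e-10, and adjusted p = 0.0435 with an estimated correlation), and 10 fell without FGF19 replicate 1. Vsig4 fell 2.21-fold, Clec4f 1.99-fold, C1qc 1.97-fold and Csf1r 1.77-fold. No other marker list was called. Of 13 endothelial markers 0 changed (camera adjusted p = 0.691), of 12 stellate markers 1 rose and 3 fell, or 1 and 5 when adjusted over the list alone (0.263) and 2 and 1 with centring on medians, 1 of 5 neutrophil markers fell (0.671), 2 of 13 lymphocyte markers fell (0.691) and 0 of 7 cholangiocyte markers changed (0.694). Of 12 hepatocyte markers 1 fell, or 7 with 1 up when adjusted over the list alone (0.263), with a median of -0.28 that was -0.12 without FGF19 replicate 1. The numbers of hepatocyte markers up and down were then 2 and 1, but 0 and 7 without FGF19 replicate 2 and 2 and 0 with centring on medians. Untested for their small number, 1 of 4 erythroid markers rose, 1 of 4 pancreatic markers fell and 1 of 3 adipose markers rose, the lipid droplet gene Cidec (2.99-fold).

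**Figure D3:**
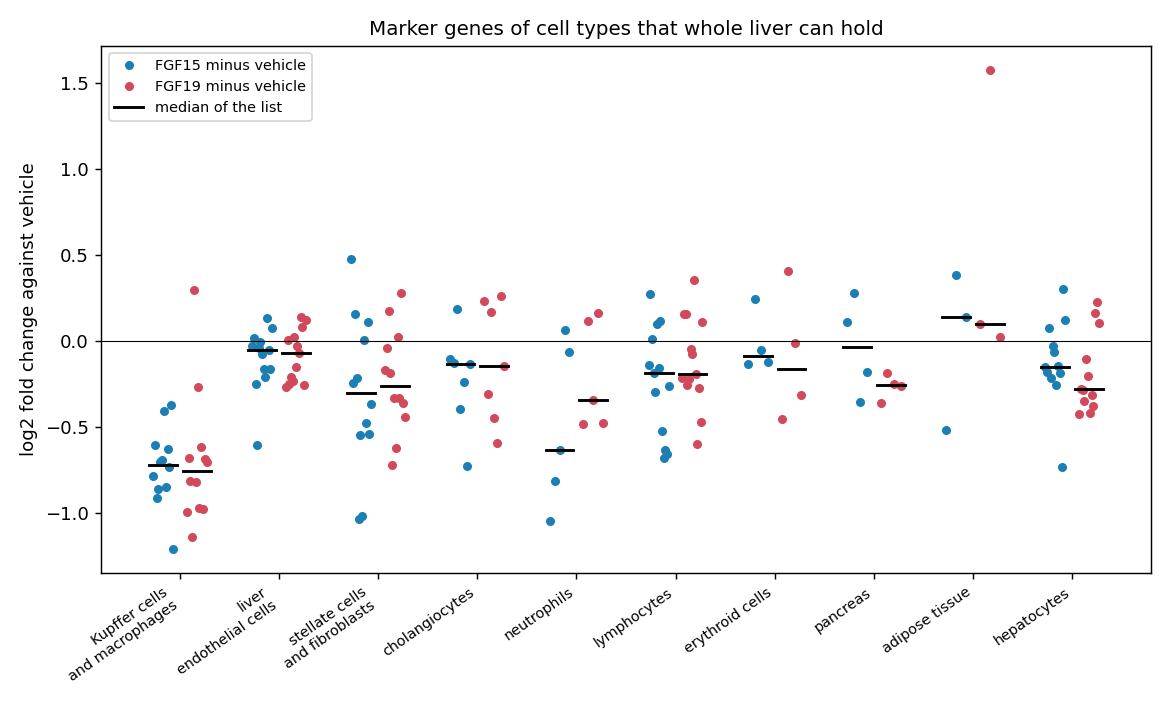
Log2 fold change against vehicle of marker genes of each cell type or tissue with FGF15 and with FGF19; points are genes and lines are the medians of the lists (2 arrays per group). The Kupffer cell and macrophage medians lie at -0.72 with FGF15 and -0.76 with FGF19, and the endothelial medians at -0.05 and -0.07, which turn positive (0.07 and 0.08) with centring on medians.

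In all, 1313 genes changed with FGF19, 609 up and 704 down, of which 55 rose and 46 fell more than 2-fold, and 11 of 25 pathway lists were called, 7 higher and 4 lower, and 0 with an estimated correlation. The stricter filter on low signals and cyclic loess each gave 9 called lists, and a pseudocount of 1 gave 10. At an unadjusted p under 0.05 there were 2728 genes. Both FGF19 arrays lay on one side of both vehicle arrays in 5681 genes (58.7%, chance 33.3%), including all 1313. Centring on medians moved the median change of all genes from -0.07 to 0.07 and gave 1218 up and 330 down. With FGF19 the log2 change on another probe set was -4.69 against -5.31 for Cyp7a1, 1.48 and 1.47 against 2.19 for Rgs16, 1.72 against 1.09 for Me1, 0.79 against 1.33 for Cd36, -0.60 against -1.14 for Socs2, -0.36 against -0.67 for Hmgcs1, 0.50 against 1.23 for Rora and -0.17 and -0.20 against -0.45 for Fgfr4. Further probe sets lay closer, at 1.16 for Cd36, -0.59 and -0.52 for Hmgcs1 and -0.40 for Fgfr4, while a dim one of Fgfr4 read -0.04. The count was 599 without vehicle replicate 1, 654 without vehicle replicate 2 and 768 without FGF19 replicate 1.

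The direct comparison of FGF19 with FGF15 tests where the responses to the orthologues differ. Igfbp1 had a mean signal of 725.6 ± 23.5 with FGF15 and 7278 ± 499 with FGF19 (SD, n = 2), 9.64-fold higher with FGF19, and Egr1 was 7.58-fold higher. Srebf1 lay at 635.0 ± 8.38 with vehicle, 387.1 ± 20.1 with FGF15 and 1029 ± 47.6 with FGF19, and Ppargc1a was 2.45-fold higher with FGF19 than with FGF15. Cyp2b9 and Cyp26a1 were 2.92-fold and 2.39-fold lower with FGF19. Cyp7a1 was 1.83-fold lower with FGF19, whereas no difference was detected for Nr0b2 (log2 difference 0.01, 95% interval -0.19 to 0.21).

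The log2 difference was 3.27 ± 0.07 for Igfbp1 (SE, adjusted p = 6e-09), which did not differ detectably between FGF15 and vehicle (-0.04, 95% interval -0.19 to 0.11), and 2.92 ± 0.09 for Egr1 (adjusted p = 1.3e-07). It was 1.34 ± 0.07 for Srebf1 (adjusted p = 5.3e-06), 1.29 ± 0.12 for Ppargc1a (adjusted p = 0.00022), -1.54 ± 0.14 for Cyp2b9 (adjusted p = 0.0002), -1.26 ± 0.11 for Cyp26a1 (adjusted p = 0.00014) and -0.87 ± 0.09 for Cyp7a1 (adjusted p = 0.00037). Dusp6 was 1.89-fold higher with FGF19 (0.92 ± 0.08, adjusted p = 0.00011) and Fasn 1.43-fold (0.51 ± 0.07, adjusted p = 0.0022). Other genes called in opposite directions against vehicle were Cdkn1a, whose rise with FGF19 rests on 1 of its 2 probe sets, and the p53 target Trp53inp1, 3.76-fold and 3.91-fold higher with FGF19 than FGF15, and Inhbe, an activin subunit, 3.31-fold lower. G6pc was higher with FGF19 by 0.32 (adjusted p = 0.045), which ended without vehicle replicate 1 (0.0876), vehicle replicate 2 (0.0882), FGF15 replicate 1 (0.246) or FGF19 replicate 1 (0.225). For Cyp8b1 (-0.23, adjusted p = 0.26), Pck1 (0.10, adjusted p = 0.6), Gys2 (0.11), Klb (-0.04), Fgfr4 (-0.18) and Fbp1 (-0.14) no difference passed. Moxd1 is not compared here, since its mean signals with both FGFs lay under the level of the filter on low signals. The difference of Tff3, low with both FGFs, did not pass either (0.63, adjusted p = 0.12), but passed without FGF15 replicate 2 (0.97, adjusted p = 0.00813).

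Genes of 3 lists stood higher with FGF19 than with FGF15. Of 18 glucocorticoid-responsive genes, 12 were higher and 0 lower, the same as when adjusted over the list alone (camera adjusted p = 2.77e-15, and adjusted p = 0.0406 with an estimated correlation). Of 18 fasting and cAMP genes, 10 were higher and 0 lower, 12 and 0 when adjusted over the list alone (camera adjusted p = 7.19e-15, and adjusted p = 0.0406 with an estimated correlation). Of 22 immediate early genes, 10 were higher and 0 lower, 12 and 0 when adjusted over the list alone (camera adjusted p = 5.47e-13, and adjusted p = 0.0406 with an estimated correlation). Besides the Kupffer cell markers against vehicle, these 3 list calls are the ones that hold with an estimated correlation. The Kupffer cell call was adjusted over 7 marker lists, these over 25 pathway lists. Some genes stand in more than 1 of these 3 lists, so the calls are not independent. Without FGF19 replicate 1 the numbers higher were 9, 9 and 7, and without either FGF15 array 7 glucocorticoid-responsive genes were higher. Examples are Sgk1 (2.31-fold), Lpin1 (2.13-fold), Id1 (2.15-fold), Btg2 (3.75-fold), Ier2 (3.04-fold) and Zfp36 (1.85-fold), and Fos differed by 1.17 (adjusted p = 0.0013). Fkbp5 did not pass (-0.02, adjusted p = 0.91).

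Lists also called higher with FGF19 than with FGF15 were inflammatory genes, with 4 of 25 higher and 0 lower (5 and 1 when adjusted over the list alone), at camera adjusted p = 0.00405 and adjusted p = 0.246 with an estimated correlation, and ribosome biogenesis, with 1 of 28 higher (2 and 0), at 0.00405 and adjusted p = 0.212 with an estimated correlation. When FGF19 replicate 1 was left out, 2 of the former and 0 of the latter were higher, and 0 of the latter were without FGF15 replicate 2 or FGF19 replicate 2. NRF2 targets had 3 of 15 higher (4 and 0), among them Gclc (2.08-fold) and Hmox1 (1.80-fold), at 0.0126 and adjusted p = 0.215 with an estimated correlation, which ended without FGF15 replicate 1 (0.0538). The cell cycle list had 1 of 21 higher (4 and 0), the inhibitor Cdkn1a, at 0.0126 and adjusted p = 0.215 with an estimated correlation, which ended with the mean of all probe sets of a gene (0.178). Gluconeogenesis had 3 of 14 higher (3 and 1), at 0.0189 and adjusted p = 0.268 with an estimated correlation, which ended without FGF19 replicate 2 (0.0684) and with the mean of all probe sets (0.0731). Called lower with FGF19 were cholesterol synthesis, with 3 of 19 lower (7 and 0 higher when adjusted over the list alone, and 1 lower with centring on medians or without either FGF15 array), at 0.00122 and adjusted p = 0.215 with an estimated correlation, and the regulators and receptors, with 3 of 14 lower (3 and 0 higher), at 0.00849 and adjusted p = 0.246 with an estimated correlation, which ended without FGF19 replicate 2 (0.0508). Without that array or FGF15 replicate 2, 1 of the regulators was lower. Among them, Nr1h4 was 1.49-fold lower with FGF19.

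No other pathway list was called between FGF19 and FGF15. Numbers higher and lower were 0 and 2 of 16 in bile acid synthesis (0 and 2 when adjusted over the list alone, camera adjusted p = 0.0662), 0 and 1 of 18 heat shock proteins (0 and 2, 0.0662), 2 and 0 of 19 in translation (2 and 1, 0.0945), 2 and 0 of 13 transporters (4 and 3, 0.114), 1 and 0 of 13 ERK targets (2 and 0, 0.114), 1 and 1 of 27 in fatty acid oxidation (2 and 3, 0.44), 2 and 4 of 21 in xenobiotic metabolism (4 and 5, 0.529) and 1 and 2 of 19 in the growth hormone axis (1 and 3, 0.691). They were 0 and 0 of 32 in oxidative phosphorylation (0 and 0, 0.728), 2 and 4 of 19 in lipogenesis (4 and 7, 0.847), 0 and 0 of 15 in glycogen metabolism (0 and 1, 0.934), 4 and 3 of 17 circadian genes (6 and 7, 0.95), 4 and 3 of 30 acute phase genes (7 and 4, 0.954), 1 and 1 of 24 in ER stress (1 and 1, 0.954) and 1 and 0 of 24 in amino acid catabolism (1 and 0, 0.954). Without FGF19 replicate 2, 11 acute phase genes were lower. When FGF19 replicate 1 was left out, the numbers were 0 and 3 in xenobiotic metabolism, 1 and 0 in translation, 0 and 1 in fatty acid oxidation, 2 and 0 in amino acid catabolism and 0 and 0 of heat shock proteins. Without FGF15 replicate 1 they were 0 and 2 in xenobiotic metabolism and 2 and 2 of acute phase genes. In lipogenesis 2 were lower without FGF19 replicate 1 or with centring on medians, 1 without FGF15 replicate 1 and 0 without FGF15 replicate 2. Within the circadian list, Dbp was 2.72-fold lower on its _s_at probe set and Rora 1.84-fold higher. Of the markers, 2 of 5 for neutrophils were higher with FGF19 (camera adjusted p = 0.0344, and adjusted p = 0.449 with an estimated correlation), S100a9 by 1.91-fold (1 of 5 without FGF15 replicate 1 or FGF19 replicate 2), and 2 of 12 for Kupffer cells were (0.67). Median, mean and test direction differed in sign for acute phase, circadian, growth hormone, ER stress, Kupffer cell and cholangiocyte genes.

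In all, 416 genes differed between FGF19 and FGF15, 233 higher and 183 lower with FGF19, of which 43 and 10 by more than 2-fold. At an unadjusted p under 0.05 there were 1612 genes. The arrays of the groups did not overlap in 4448 genes (45.9%, chance 33.3%), including all 416. Centring on medians gave 252 higher and 141 lower. Without FGF19 replicate 1 the number was 234.

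The mean of both FGFs was set against vehicle. This average does not separate genes that responded to both from those that responded mainly to one. Cyp7a1 had a log2 change of -4.87 ± 0.08 over both FGFs (SE, with 4 arrays against 2). Moxd1 and Tff3 fell too, but the sizes depend on the offset because signals with FGF were low. Next were Orm2 (3.59-fold) and Slc22a7 (3.50-fold). Egr1 (7.53-fold, from log2 changes of 1.45 with FGF15 and 4.37 with FGF19), Rgs16 (4.87-fold), Cyp4a14 (3.85-fold), Gsta2 (3.21-fold) and Acot3 (3.20-fold, _s_at probe set) rose most. Fatty acid oxidation (16 of 27 up, 0 down) and ER stress (13 of 24 up, 1 down) stood first among the lists (camera adjusted p = 6.11e-14 and 4.93e-11, and adjusted p = 0.0568 for each with an estimated correlation).

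Of the genes called with each FGF, 344 rose with both and 342 fell with both, where independent lists of these sizes would share 36.0 and 47.0. Part of this excess can come from the shared vehicle arrays. A further 30 moved in opposite directions, all 30 of them called in the direct comparison. Of 502 genes called with FGF15 but not FGF19, 100 differed between the FGFs, as did 162 of 597 called with FGF19 but not FGF15. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.691 (Spearman's rho 0.652) and 75.5% had the same sign. Unchanged groups simulated against the same vehicle arrays gave r = 0.499 and 66.7%. In 20 simulations they gave 0 shared calls, but with a mean of 0.75 and 0.5 calls per comparison this says nothing of how many shared calls come from the vehicle arrays. The covariance was 0.0679 against 0.0113 in simulations, a difference of 0.0567. With FGF15 set against one vehicle array and FGF19 against the other, so that none is shared, r was 0.493 or 0.465, where 100 simulations of unchanged groups gave -0.028 to 0.029. All these simulations drew the noise of each gene independently, so they leave out variation that genes share within an array. Srebf1, Cdkn1a, Trp53inp1, Inhbe and Tnfrsf12a, the receptor of TWEAK, were among the 30 genes with opposite changes. Tnfrsf12a fell 2.37-fold with FGF15 and rose 1.80-fold with FGF19, the rise being lost without vehicle replicate 1 (0.125), FGF19 replicate 1 (0.103) or FGF19 replicate 2 (0.0828). For Inhbe the fall with FGF19 was lost without vehicle replicate 1 (0.062) and with centring on medians (0.0531).

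**Figure D4:**
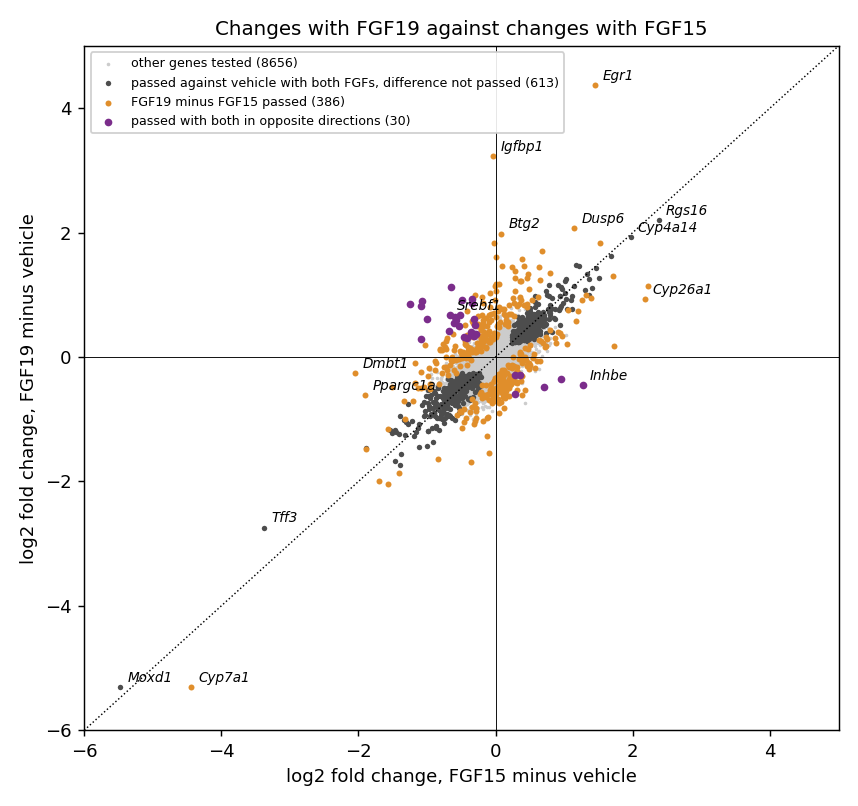
Log2 fold change against vehicle with FGF19 (vertical) and with FGF15 (horizontal) for each gene, coloured by whether the gene was called in the same or in opposite directions, or differed between FGF19 and FGF15; the dotted line marks equal changes (2 arrays per group). Cyp7a1 lies at -4.44 and -5.31, Egr1 at 1.45 and 4.37, and Igfbp1 at -0.04 and 3.23.

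In all, 1461 genes changed over both FGFs, 678 up and 783 down, with 2877 at an unadjusted p under 0.05, and 10 pathway lists were called. All FGF arrays lay on one side of both vehicle arrays in 3460 genes (35.7%, chance 13.3%), including 1380 of the 1461. Besides the first pair, lipogenesis (3.55e-06), immediate early genes (0.00315), oxidative phosphorylation (0.0191) and xenobiotic metabolism (0.0287) were called higher, and bile acid synthesis (0.00509), cholesterol synthesis (0.0261), cell cycle (0.0261) and the growth hormone axis (0.0352) lower. Of these, immediate early genes and cholesterol synthesis were called with FGF19 but not with FGF15 (adjusted p = 0.828 and 0.294), and the cell cycle and xenobiotic metabolism with FGF15 but not with FGF19 (0.284 and 0.0517). None of these 10 calls held with an estimated correlation, and the stricter filter on low signals gave 8 called lists. Cholesterol synthesis and the growth hormone axis lost theirs without vehicle replicate 2 (0.0811 and 0.196) or FGF15 replicate 1 (0.0561 and 0.0969) and with centring on medians (0.0767 and 0.0571), oxidative phosphorylation without vehicle replicate 1 (0.14), xenobiotic metabolism without FGF19 replicate 2 (0.157) and the cell cycle with the stricter filter (0.434). Centring on medians gave 1374 up and 385 down, and the count was 612 without vehicle replicate 1 and 719 without vehicle replicate 2.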

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

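The tests of cyclic loess, of a corticosteroid response, of a lower share of all non-parenchymal cells and of fewer Kupffer cells were chosen only after the data were seen.

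The log2 effects of FGF19 and FGF15 against vehicle were called in opposite directions, with a difference that itself passed the test, in 12 named genes. FGF19 minus FGF15 was 2.09 for Tnfrsf12a, 1.97 for Trp53inp1, 1.91 for Cdkn1a, 1.34 for Srebf1, 1.28 for Cebpd, 1.24 for Gadd45b, 1.21 for Sgk1, 1.04 for Zbtb16, 0.71 for Cebpb and 0.66 for Abcg5. It was -1.72 for Inhbe and -1.31 for G0s2. The difference passed for each of them with any one array left out, and all calls against vehicle held for Trp53inp1, Cdkn1a and Srebf1. The rise of Cdkn1a with FGF19 rests on 1 of its 2 probe sets, since the other read 0.18 against 0.82 (its fall with FGF15 was -1.35 there), as do those of Cebpb (0.06 against 0.30) and Zbtb16 (0.12 against 0.50). Dimmer probe sets of Gadd45b and Cebpd gave smaller changes with FGF19 (0.36 and 0.11, and -0.02), as did the other probe sets of Tnfrsf12a (0.67 against 0.85, unadjusted p = 0.11, an _x_at probe set) and Trp53inp1 (0.45 against 0.89). At least 1 call against vehicle ended for each of the others when single arrays were left out. Without vehicle replicate 1 the adjusted p with FGF19 was 0.125 for Tnfrsf12a, 0.062 for Inhbe, 0.0666 for G0s2, 0.132 for Cebpb, 0.0667 for Gadd45b and 0.0579 for Zbtb16, and with FGF15 it was 0.0981 for Cebpd, 0.109 for Gadd45b, 0.0618 for Sgk1, 0.0846 for Zbtb16 and 0.189 for Abcg5. Without vehicle replicate 2 it was 0.072 for Gadd45b, 0.0894 for Zbtb16 and 0.134 for Abcg5 with FGF19, and 0.106 for Cebpd, 0.0852 for Gadd45b, 0.243 for Sgk1 and 0.0541 for Abcg5 with FGF15. Without FGF15 replicate 1 it was 0.0973 for Gadd45b, 0.183 for Sgk1, 0.0514 for Zbtb16 and 0.0972 for Abcg5, and without FGF15 replicate 2 it was 0.0914 for Cebpd and 0.0743 for Abcg5, all with FGF15. Without FGF19 replicate 1 it was 0.103 for Tnfrsf12a, 0.127 for Gadd45b, 0.125 for Zbtb16 and 0.122 for Abcg5 with FGF19 and 0.0714 for Sgk1 with FGF15, and without FGF19 replicate 2 it was 0.0828 for Tnfrsf12a with FGF19 and 0.0709 for Sgk1 with FGF15. Zbtb16 was read on an _x_at probe set, which can bind related transcripts. On FGF19 replicate 1 the control probe set for 18S rRNA, which no comparison uses, read 32.3 against 5.80 and 5.44 on the vehicle arrays.

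Immediate early genes were higher with FGF19 than with FGF15, with a median log2 difference of 0.485 over the list. Degraded RNA on FGF19 replicate 1 as the whole cause is argued against, because with FGF19 replicate 2 as the only FGF19 array the median was 0.547 and 7 of the 10 members were still called. Scaling between arrays as the whole cause is argued against by a median of 0.515 after cyclic loess. A corticosteroid response to handling of the FGF19 mice stays open. Of the 14 glucocorticoid-responsive genes outside the immediate early and cAMP lists, 8 were called higher with FGF19. With 12 of all 18 already called higher, this count could not have been lower, so it adds no support. Fkbp5, a direct target of the glucocorticoid receptor, was not called. A stronger or longer response to FGF19 than to FGF15, at doses that the labels do not give, may also account for the pattern and was not tested.

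Kupffer cell and macrophage markers were lower with both FGFs. Scaling as the whole cause is argued against, since the list's median was -0.674 with arrays centred on their medians and -0.806 without. An equal fall of all non-parenchymal cells is argued against by the 13 endothelial markers, whose median was -0.115. The standard error of their mean over members, 0.041, treats genes as independent and does not measure the spread between arrays. Stellate cell markers (median -0.304, 0 of 12 up and 4 down) and neutrophil markers (-0.348, 3 of 5 down) lay between, so a smaller fall of other non-parenchymal cells stays open. Fewer Kupffer cells, or less of their RNA per cell, also stays open and could not be tested on whole-liver RNA, since 11 of the 12 members lying lower on all 4 FGF arrays than on both vehicle arrays only restates the pattern.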

How the results depend on the processing

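Cyclic loess was chosen only after the data were seen. These tallies leave out the threshold of 0.10 and the fit of all probe sets. Over the other alternatives, named genes kept their side of the threshold in 10892 comparisons with the reported value, fell short of it in 748, newly passed in 146 and reversed in 1. The mean of both FGFs was not counted for genes. Direction was compared only where the gene passed in the main fit or in the alternative. Changes of sign in genes that passed in neither are not counted. Called pathway lists kept their direction and call in 762 and lost the call in 45. That tally leaves out marker lists, fry and camera with an estimated correlation, with which most calls were lost. The reversal was Atp5c1, read on an _s_at probe set, with FGF15, at -0.178 (adjusted p = 0.184) with the mean of all probe sets, where its other probe set moved the other way. Without an intensity trend in the prior the numbers of changed genes were 635 for FGF15, 731 for FGF19, 163 for FGF19 against FGF15 and 896 for the mean of both; the cause was not tested. A threshold of 0.10 gave 699 genes between the FGFs, and all probe sets gave 2235 for the mean of both, with more features tested. With an estimated correlation camera called 0, 0, 3 and 0 pathway lists, and fry, which asks a different question, called 16 for the mean of both. Since the estimate lay under the preset value for some lists that lost their call, a higher correlation does not explain every loss. The correlation of the effects was 0.633 with a pseudocount of 1 and 0.493 or 0.465 with the vehicle arrays split; the cause of the former was not tested. Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 538 to 1199 genes for FGF15, 599 to 1359 for FGF19, 234 to 341 between the FGFs and 612 to 1449 for the mean, with 10 to 13, 10 to 12, 10 to 12 and 8 to 11 lists, and a correlation of 0.601 to 0.742. The lowest gene counts came without vehicle replicate 1, or without FGF19 replicate 1 between the FGFs, and fewer arrays were then in the fit. With the replicate number as a block the counts were 1246, 1380, 450 and 1530. Same-numbered arrays of vehicle and FGF15, vehicle and FGF19, and FGF15 and FGF19 deviated from their group means with correlations of 0.081, -0.022 and 0.05. The labels give the arrays a shared number but state no pairing, and these correlations do not exclude one. Between 36.4% and 41.5% of probe sets per array read under 32, where fold changes are understated.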

Other observations

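Within some lists single members moved in opposite directions. Among transporters, a list called in no comparison, Abcc3, a basolateral exporter of conjugated bile acids, was higher with both FGFs (log2 change 0.79 with FGF15 and 0.84 with FGF19) and Slco1a4, an uptake transporter, lower (-0.71 and -0.76), each past the test. Among the heat shock proteins, a list called higher with FGF15 at the preset correlation alone, the co-chaperone gene Chordc1 was higher (0.67 and 0.52) and Hspb1 lower (-0.62 and -0.70) with both. Socs2, a feedback inhibitor induced by growth hormone, was lower with FGF19 (-1.14) than with FGF15 (difference -0.64, adjusted p = 0.0032). Retinoic acid hydroxylase Cyp26a1 was higher with both FGFs but less so with FGF19, at mean signals of 132.1 with vehicle, 709.1 with FGF15 and 277.7 with FGF19.

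By a criterion chosen after the data were seen, 2 of all genes had a vehicle mean signal above 400 and read under 50 on all 4 FGF arrays, Moxd1 and Tff3. With synthesis stopped at the injection, the mean log2 changes over both FGFs after 6 h allow mRNA half-lives of at most 1.11 h for Moxd1 (-5.389), 1.23 h for Cyp7a1 (-4.873) and 1.96 h for Tff3 (-3.063). These are computed from the fold changes on the log2(signal + 32) scale and are not measured half-lives. They are not bounds for each FGF. Cyp7a1 with FGF19 (-5.31), and Moxd1 and Tff3 with FGF15, fell by more than the mean, which requires shorter half-lives.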
